A study of Mus musculus with 4 samples.

How the data were processed

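Poly(A)-selected RNA of splenic CD8 T cells was made into strand-specific libraries and sequenced on an Illumina HiSeq instrument, per the labels' protocols. Each of the 4 groups (naive, LCMV-Armstrong, LCMV-CL13 CXCR5+ and LCMV-CL13 CXCR5-) was 1 library. The submitters' processing notes name Bowtie 1.0.0, TopHat2, Cufflinks 2.1.1, Cuffdiff and the mouse build GRCm38; how each was set is not given in the sources used here. The deposited values are read as FPKM made by the authors with these tools; the file header names no unit, and the unit was taken from the tools and the values. FPKM divides by transcript length and library size, so depth is unknown and no counting error was computed. An exact 0 can be a failed estimate and is described as listed at 0. Since 1 library per group gives no spread, no test was run and no p-value is given.

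Columns were matched to groups by name. The column headed Effector was given to the Armstrong library by elimination, since no label uses that word; every comparison with the Armstrong group rests on this. No column of values in the table analysed was left unused (0); a second file that the labels name was not used here. The table held 41386 rows, of which 23871 were 0 in all libraries. The 6 rows without a gene name were left out and held at most 0.00038% of a library's FPKM. Rows with a mean of at least 1 FPKM over the 4 libraries were analysed (11971).

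For each of 6 pairwise comparisons the log2 ratio was formed with a pseudocount of 1 FPKM, and rows at least 2-fold apart were counted. Named genes were the 12 highest and 12 lowest ratios of the CXCR5+ against CXCR5- comparison and the 6 highest and 6 lowest of each other one, among genes with at least 5 FPKM in the higher library. Unnamed models, small RNAs, histones, immunoglobulin and T cell receptor segments, mitochondrial genes and pseudogenes could not be named; in the first comparison 131 such rows lay above the last named gene and 55 below. Genes whose symbol stood on 2 or more rows were not named either. Some genes that the rule or the lists name are not reported here. For each list described, 2 to 4 members furthest apart with at least 5 FPKM in the higher library could be named besides, and members that a sentence on the labels or another list needed; others are said to be named after their values were seen, or are printed for a library beside one in which the rule names them. The 27 gene lists (18 of T cell programs and 9 of other cells), the comparisons, the naming rule and the 7 alternatives for each result, with 1 more for lists, were fixed before the data were examined.

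The median log2 ratio of a list was placed among 10000 random lists of as many named genes, matched in 20 bins of mean expression. The percentile describes these libraries and is not a p-value. List genes not found under their symbol were not analysed here. Transcript length and GC content were medians over a gene's protein-coding transcripts, or all transcripts where it has none, in GENCODE release M21, which uses the same build, and were found for 94.5% of the analysed rows. Coordinates come from the same annotation and count from 1. Of 51 named genes, 49 had a single position and 15 of these shared their strand with another annotated gene.

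The alternatives fixed beforehand were pseudocounts of 0.1 and 5, no filter on low values, a mean of at least 5 FPKM, equal library sums, ratios centred on the median gene with a mean of at least 10 FPKM, equal upper quartiles and, for lists, random lists not matched on expression. Removal of the GC trend, removal of the length trend, a count of named genes alone, the follicular helper list without Cxcr5 and Pou2af1 and a second set of 18 myeloid and 6 plasma cell markers, taken with no filter, were added after seeing the data. Trends were medians in 20 bins of genes with a mean of at least 5 FPKM.

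The steps were tested on simulated data made from 9787 real genes for the CXCR5+ against CXCR5- comparison. The simulated noise was a chosen value, the same at all expression levels, with no RNA of other cells. The counts that follow check the steps and are not error rates of the real ratios. Of 200 genes set 4-fold apart, 193 were found and 2 unchanged genes were counted as 2-fold apart. With a GC trend added, 316 unchanged genes were counted before and 2 after its removal. Of 200 lists of 20 genes shifted 1.5-fold, 199 lay outside the 2.5 to 97.5 percentile range, and of 200 unshifted lists 8 did. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.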

Results

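RNA was sequenced from CD8 T cells of the spleens of C57BL/6 mice in 4 libraries, with 1 library in each group. The groups were naive cells from uninfected mice, cells from mice infected with the Armstrong strain of lymphocytic choriomeningitis virus (LCMV), and CXCR5+ and CXCR5- cells from mice infected with LCMV-CL13. Armstrong is the strain commonly used for acute infection and clone 13 the one used for persistent infection. The series design names the comparison of the CXCR5+ and CXCR5- subsets in chronic infection. Expression was given in FPKM for 41386 rows, of which 11971 had a name and a mean of at least 1 FPKM over the libraries. FPKM summed to 678583 in the naive, 757358 in the Armstrong, 644333 in the CXCR5+ and 704528 in the CXCR5- library. Read depth is unknown, so no counting interval was given. With 1 library per group no difference has a replicate check, no test was run, and higher or lower describes these libraries alone. A fold is the ratio of FPKM + 1 and understates the difference of low genes.

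The transcript of the sorted receptor followed the labels of the subsets. Cxcr5, on chromosome 9 from 44511787 to 44561877 (GRCm38), was at 5.83 FPKM in the CXCR5+ and 0.920 FPKM in the CXCR5- library. It was at 9.85 FPKM in the naive and 0.710 FPKM in the Armstrong library. Immunoglobulin segments made up 6.28% of FPKM in the CXCR5+ library. Which cells the Cxcr5 transcript came from was not tested, so its value is no check of the T cells alone. Cd8a was at 513, 584, 398 and 499 FPKM in the naive, Armstrong, CXCR5+ and CXCR5- libraries. The 10 CD8 T cell identity and sort genes had a median log2 ratio of -0.01 between CXCR5+ and CXCR5- cells, at percentile 66.1 of 10000 random lists matched on expression. The Armstrong library was assigned the column headed with the word Effector, since the other 3 columns carry the names of the other groups.

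The first comparison asks which transcripts set CXCR5+ apart from CXCR5- cells of the LCMV-CL13 infection. The inhibitory receptors Lag3, at 247 against 115 FPKM, and Tigit, at 382 against 228 FPKM, were higher in the CXCR5+ library, while Ptger4, a prostaglandin receptor, at 9.57 against 18.3 FPKM, and the chemokine receptor Cxcr6, at 88.2 against 149 FPKM, were lower. The list of inhibitory and exhaustion associated genes had a median log2 ratio of 0.30, at percentile 99.4, or 0.20 at percentile 96.7 with a mean of at least 5 FPKM, with 1 of its 19 measured genes at least 2-fold higher, 0 at least 2-fold lower and 18 under 2-fold apart. The 1 was Lag3, at a log2 ratio of 0.94 with the trend on transcript GC content removed. Of the cytotoxic effector list, the receptors Klrk1, at 70.9 against 186 FPKM, and Klrd1, at 109 against 263 FPKM, were lower, at log2 ratios of -0.96 and -0.68 with the GC trend removed. Ifng, the gene of interferon gamma, was at 54.7 against 148 FPKM and Ccl4 at 209 against 436 FPKM, a log2 ratio of -1.06 that was -0.93 with equal sums and -0.99 with the ratios centred on the median gene. Beside all of these, markers of plasma cells and myeloid cells were higher in the CXCR5+ library, with median log2 ratios of 2.73 and 2.99. Which cells the transcripts of the program lists came from was not tested, so their ratios need not be of T cells alone.

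Of 25 measured cytotoxic effector genes, 5 were at least 2-fold lower in the CXCR5+ library and 0 at least 2-fold higher. The 5 were Klre1, S1pr5, Klrk1, Klrd1 and Zeb2. S1pr5, a receptor of T cell egress, was at 39.7 against 116 FPKM, and Zeb2, a transcription factor of terminal effector cells, at 14.9 against 35.3 FPKM. The granzymes, named after their values were seen, were closer, with Gzmb at 908 against 1095 FPKM and Gzma at 768 against 815 FPKM. The median of the whole list was -0.22, at percentile 19.2, so the list did not stand apart from matched random lists.

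The follicular helper list had a median log2 ratio of 0.30, at percentile 97.8, with 3 of 14 genes at least 2-fold higher (Pou2af1, Cxcr5 and Il6ra) and 2 at least 2-fold lower (Btla and Sh2d1a). With the GC trend removed the median was 0.50, at percentile 99.95, with 4 genes higher and 0 lower, since Btla was at -0.66 and Sh2d1a at -0.70. With a pseudocount of 5, Cxcr5 (0.87), Il6ra (0.58), Btla (-0.86) and Sh2d1a (-0.995) were under 2-fold, as was Sh2d1a with equal sums (-0.92) and centred ratios (-0.97). Cxcr5 defined the sort and Pou2af1 is also a gene of B lineage cells. Without both, the median of the other 12 genes was 0.19, at percentile 90.4, and the whole list also left the upper tail with a pseudocount of 5 (0.16), a mean of at least 5 FPKM (0.19) and equal sums (0.40). Bcl6, a transcription factor of follicular helper cells named after its values were seen, was at 3.76 against 1.57 FPKM. Among naive and memory associated genes, Xcl1 was at 90.9 against 37.7 FPKM, while Il7r was at 15.2 against 33.9 FPKM, a log2 ratio of -1.10 that was -0.57 with the GC trend removed, -0.94 with a pseudocount of 5 and -0.98 with equal sums. Tcf7 and Id3 were named after their values were seen: Tcf7 was at 68.6 against 66.9 FPKM and Id3 at 4.08 against 3.87 FPKM, and this list of 22 genes had a median of -0.09 at percentile 47.7.

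Glycolysis genes had a median log2 ratio of 0.47, at percentile 100, with 1 of 18 genes, Slc16a3, at least 2-fold higher and 0 at least 2-fold lower; Slc16a3 was at 0.94 with the GC trend removed and 0.86 with a pseudocount of 5. Pgam1 was at 53.8 against 30.2 FPKM, Tpi1 at 122 against 70.2 FPKM and Pkm at 650 against 395 FPKM. DNA replication genes had a median of 0.17 at percentile 98.5, or 0.12 at percentile 97.3 with a pseudocount of 5, with 1 of 29 genes at least 2-fold lower, Pcna, and 0 at least 2-fold higher; with the GC trend removed Pcna was at -0.96 and 1 other gene, Rrm1, named after its values were seen, was higher at 1.07. The 35 cytoplasmic ribosomal protein genes had a median of -0.38 at percentile 0.620, and each was under 2-fold apart. T cell receptor induced early response genes had a median of -0.23 at percentile 16.3, or -0.36 at percentile 1.94 with the GC trend removed, and went both ways: Fos was at 25.2 against 68.2 FPKM and Cd69 at 12.2 against 28.6 FPKM, while Irf4 was at 17.2 against 7.23 FPKM and Nr4a1 at 15.2 against 6.78 FPKM. Cd69 and Nr4a1 were under 2-fold with the GC trend removed (-0.83 and 0.85), and Cd69, Irf4 and Nr4a1 with a pseudocount of 5 (-0.96, 0.86 and 0.78). The medians of the remaining program lists lay between percentiles 2.5 and 97.5. They were 0.13 for cytokines, 0.07 for chemokines and homing receptors, 0.00 for costimulatory receptors, -0.02 for E and Id proteins, 0.02 for transcription factors of T cell differentiation, 0.15 for mitosis genes, -0.09 for interferon stimulated genes, 0.09 for nuclear respiratory chain genes and -0.10 for Bcl2 family and death receptor genes. Of these, mitosis genes entered the upper tail with a pseudocount of 5 (0.13), a mean of at least 5 FPKM (0.17) and the GC trend removed (0.19), and chemokines and homing receptors with the GC trend removed (0.26, percentile 99.96).

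Genes of myeloid cells and of antigen presentation were among those furthest apart between the subsets. Of the 12 named genes highest in the CXCR5+ over the CXCR5- library, Lyz2, the gene of lysozyme in myeloid cells, was at 289 against 3.35 FPKM, a 66.7-fold ratio. Fcgr4, an Fc receptor of myeloid cells, was 55.2-fold higher, a log2 ratio of 5.79 that was 3.72 with a pseudocount of 5 and 7.93 with one of 0.1, Csf1r 30.1-fold and Spi1 30.6-fold. The others were Cd74 at 41.7-fold, H2-Eb1 at 32.1-fold and H2-Aa at 31.9-fold, genes of antigen presentation by MHC class II, with Chil3, Slpi, Mzb1, Ace and Ifitm2. For these 3 the CXCR5+ library lay near the naive one and the CXCR5- library was low: Cd74 was at 694 FPKM in the CXCR5+, 15.7 FPKM in the CXCR5- and 549 FPKM in the naive library. Ace was listed at 0 in the CXCR5- library and at 26.4 FPKM in the CXCR5+ library. Of the 13 measured myeloid markers, 11 were at least 2-fold higher and the median log2 ratio was 2.99, at percentile 100, or 1.31 with a pseudocount of 5 and 1.92 with no filter on low values. All 6 measured plasma cell markers were at least 2-fold higher, with a median of 2.73 at percentile 100, or 1.54 with a pseudocount of 5, 4.10 with one of 0.1 and 4.16 with a mean of at least 5 FPKM; Mzb1 was at 79.4 against 1.81 FPKM and Igj, the J chain gene, at 94.1 against 4.31 FPKM.

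The B cell list had 6 of 7 measured genes at least 2-fold higher and a median of 4.46, at percentile 100, or 0.50 with no filter on low values, but 4 of the 7 are MHC class II genes or Cd74, which myeloid and dendritic cells also express. The 6 higher genes therefore also included some outside these 4. Ms4a1, a gene of the list but not among the 7 measured, was listed at 0 in both subsets. Erythroid and platelet markers had a median of 1.12 at percentile 99.99, which was 0.46 with no filter, 0.49 with a pseudocount of 5, 1.96 with one of 0.1 and 3.15 with a mean of at least 5 FPKM. NK cell markers had a median of 0.49 at percentile 98.4, or 0.78 with a mean of at least 5 FPKM and 0.28 with no filter, which lay within the 2.5 to 97.5 percentile range, with Tyrobp and Fcer1g, which myeloid cells express too, as the 2 genes at least 2-fold higher. Dendritic markers had a median of 0.16 at percentile 79.1, and the 3 measured CD4 T cell markers 0.13 at percentile 73.7. Of the stromal list Pecam1 alone was measured, at 53.7 against 50.4 FPKM, and of the gamma delta T cell list the receptor segments Tcrg-C1, at 2.33 against 6.01 FPKM, and Tcrg-C2, at 13.3 against 22.9 FPKM, so no median was formed.

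**Figure D1:**
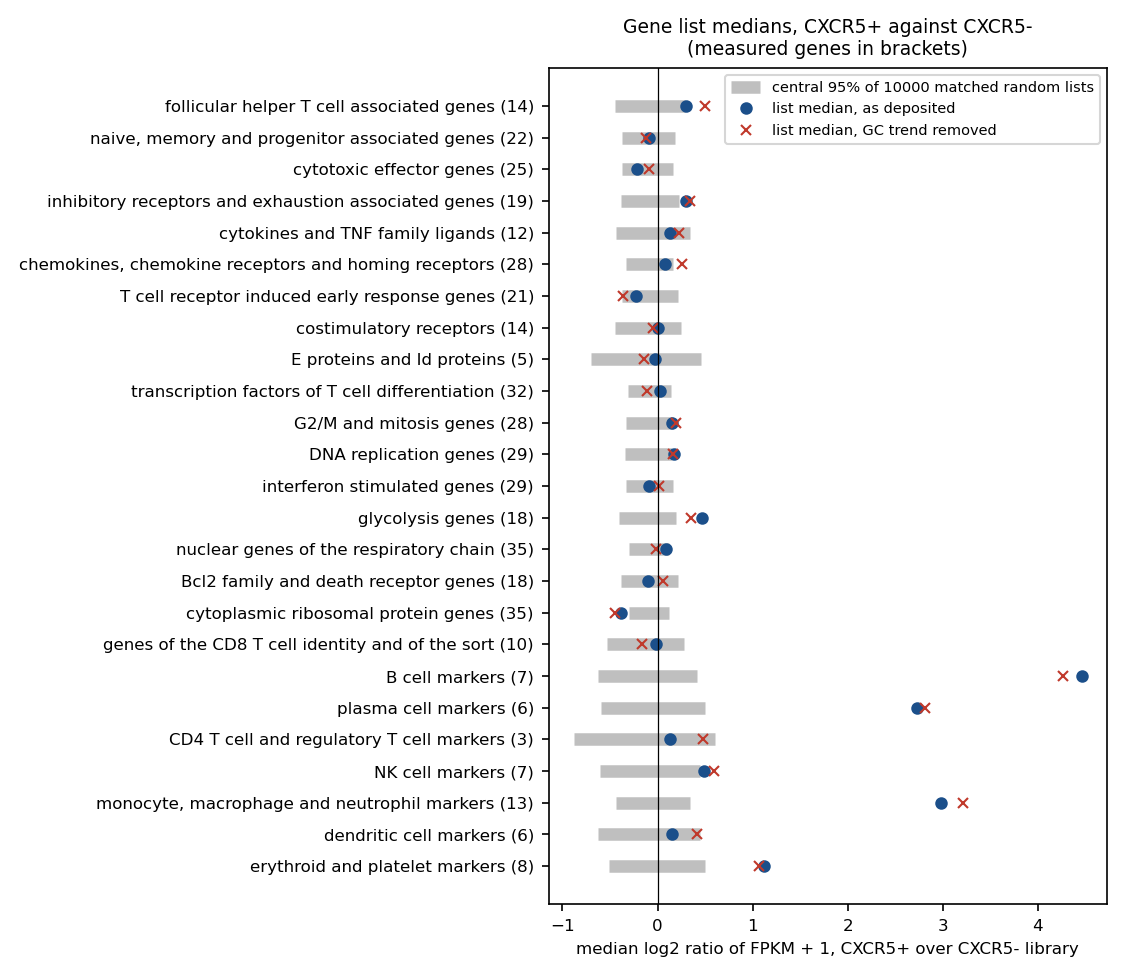
Median log2 ratio of FPKM + 1 between the CXCR5+ and CXCR5- libraries for each gene list, as deposited (circles) and with the trend on transcript GC content removed (crosses). Grey bars span the 2.5 to 97.5 percentiles of 10000 random lists matched on expression; the plasma cell and myeloid lists lie at 2.73 and 2.99, right of their bars.

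The 12 named genes lowest in the CXCR5+ library were Klrc3, Insl3, Klhdc1, Snhg6, Gadd45a, Erdr1, Tmsb15l, Zfc3h1, Zfp932, Abcd3, Gnl2 and Tmem184c, at ratios from 13.5-fold to 5.11-fold lower. Klrc3, on chromosome 6 from 129639064 to 129643337, has close paralogs, so its value is uncertain. Insl3 lies on chromosome 8 from 71689214 to 71690575 within the same-strand gene Jak3, so reads of both are hard to part. Mzb1, Ifitm2, Itgam, Snhg6 and Tmsb15l also share their strand with another annotated gene. So do Abcd3, Zfc3h1, Gnl2, Cd74, Csf1r, Fcgr4 and Slpi, with unnamed models, a pseudogene or small RNAs. In all, 724 rows were at least 2-fold higher and 1099 at least 2-fold lower in the CXCR5+ library. Among the 9787 rows that are genes with their own symbol, leaving out immunoglobulin and T cell receptor segments, unnamed models and small RNAs, the counts were 386 and 716. The ratios followed transcript GC content, with Spearman rho 0.36 across 8415 genes and medians from -0.48 in the 1683 genes with the least GC to 0.11 in the 1683 with the most; genes are not independent replicates.

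**Figure D2:**
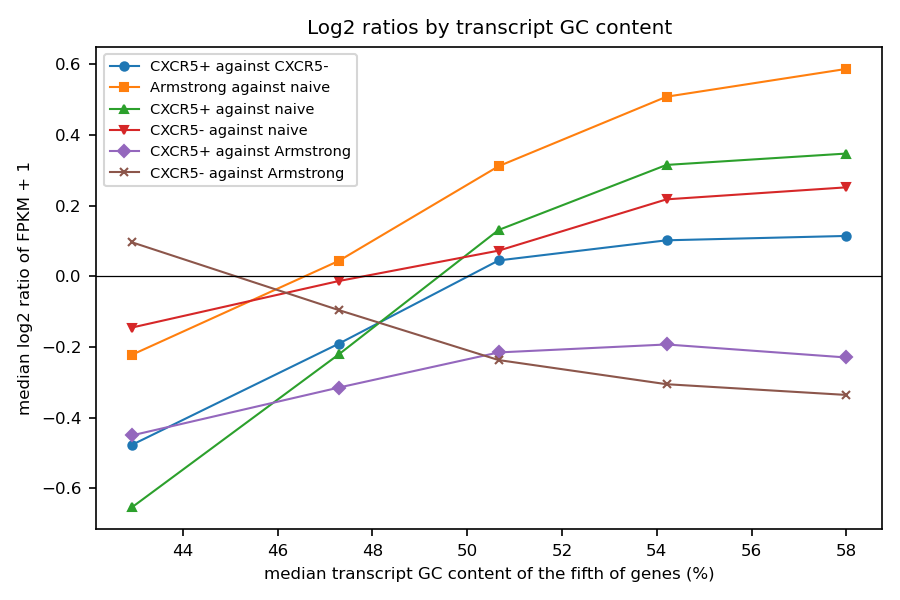
Median log2 ratio of FPKM + 1 in 5 groups of 1683 genes ordered by transcript GC content (%), 1 line for each of the 6 comparisons, over 8415 genes with a mean of at least 5 FPKM. The CXCR5+ against CXCR5- line runs from -0.48 in the group with the least GC to 0.11 in that with the most.

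Armstrong infection was then compared with the naive state. Effector transcripts were higher in the Armstrong library: Gzmb was at 1314 against 32.2 FPKM, Gzma at 1926 against 60.9 FPKM and S100a4 at 1022 against 38.6 FPKM. Of 25 cytotoxic effector genes 21 were at least 2-fold higher and 0 at least 2-fold lower, with a median log2 ratio of 2.54 at percentile 100. All 28 mitosis genes were at least 2-fold higher, with a median of 2.99 at percentile 100, or 1.98 with a pseudocount of 5, as were 21 of 29 DNA replication genes, at 1.62 and percentile 100. Naive and memory associated genes were lower, with 12 of 22 at least 2-fold lower, 1 at least 2-fold higher and a median of -1.31 at percentile 0: the homing receptor Ccr7 was at 2.24 against 116 FPKM and Il7r at 19.4 against 308 FPKM.

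Beyond these, Lgals3 was 46.9-fold and Itgam 40.6-fold higher, Tigit was at 134 against 3.32 FPKM, and the metallothionein genes Mt1 and Mt3 were at 51.7 and 63.4 FPKM and listed at 0 in the naive library. Dapl1 was at 110 FPKM in the naive library and listed at 0 in the Armstrong library, as was Apol7c at 30.7 FPKM. Auts2 at 317 FPKM and Snhg9 at 38.3 FPKM in the naive library were listed at 0 in the other 3. The Snhg9 locus holds a small nucleolar RNA on the same strand, and the Auts2 locus holds unnamed models on its strand. Inhibitory and exhaustion associated genes had a median of 0.86 at percentile 99.5, or 1.63 with a mean of at least 5 FPKM, with 9 of 19 at least 2-fold higher. The naive library also held MHC class II transcripts, with Cd74 at 549 FPKM against 142 FPKM, and Clec9a, a dendritic cell marker, at 12.8 against 0.175 FPKM, while Itgax was at 16.5 against 266 FPKM; the B cell and dendritic lists had medians of -1.95 and -1.63, at percentiles 0 and 0.010, or -0.56 and -0.60 with no filter. The dendritic median was -0.71 with a pseudocount of 5, -2.73 with one of 0.1 and -0.18, at percentile 16.2, with a mean of at least 5 FPKM. Myeloid markers went the other way, at 0.79 and percentile 98.5, with 5 of 13 at least 2-fold higher and 0 at least 2-fold lower. With the GC trend removed they were at 0.43 and percentile 85.6. Which cells the transcripts came from was not tested, so ratios to the naive library need not be of T cells alone.

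In all, 2148 rows were at least 2-fold higher and 1348 at least 2-fold lower in the Armstrong library. The median gene with a mean of at least 10 FPKM was at 0.32 on the log2 scale, and with the ratios centred on it the counts were 1329 and 2177, so which side holds more genes rests on the scaling; with equal upper quartiles they were 1404 and 2029.

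Each LCMV-CL13 subset was compared with naive cells. Inhibitory receptors stood out in both: Pdcd1, the gene of PD-1, was at 95.7 FPKM in the CXCR5+, 80.4 FPKM in the CXCR5- and 2.32 FPKM in the naive library, and Tigit was 88.6-fold and 53.0-fold higher than in naive cells. The list had 14 of 19 genes at least 2-fold higher in CXCR5+ cells and 13 in CXCR5- cells, with medians of 1.68 and 1.60, both at percentile 100. Cytotoxic effector genes had medians of 2.07 and 2.21, with 18 and 20 of 25 genes at least 2-fold higher, and mitosis genes 2.43 and 2.30, with 25 and 26 of 28, all 4 at percentile 100; with a pseudocount of 5 both mitosis medians were 1.51. Naive and memory associated genes had medians of -1.44 and -1.36, both at percentile 0, with 14 of 22 at least 2-fold lower in each subset. Dapl1 was at 2.15 and 2.04 FPKM against 110 FPKM, and Tcf7 at 68.6 and 66.9 FPKM against 391 FPKM.

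The follicular helper list was at -0.27 and percentile 34.8 in CXCR5+ cells and at -1.38 and percentile 0 in CXCR5- cells. This gap rested on the filter, since with a mean of at least 5 FPKM the medians were -2.43 and -2.28, both at percentile 0, and with no filter the CXCR5- median was -0.25 at percentile 19.4; the difference between the subsets was not tested. The other named genes were Chil3, Lag3, Fcgr4, Mzb1, Tdrp, Igfbp4 and Ccr7 for the CXCR5+ subset and Lgals3, Prr5, Gzmb, Igfbp4 and H2-Aa for the CXCR5- subset, besides Mt1, Auts2 and Snhg9 in both and Mt3 in the latter. Plasma cell markers had a median of 2.60 at percentile 100 in the CXCR5+ and 0.06 at percentile 59.5 in the CXCR5- library, the former 1.79 and 3.84 with pseudocounts of 5 and 0.1 and 3.60 with a mean of at least 5 FPKM, and myeloid markers 2.27 at percentile 100 and -0.64 at percentile 1. The former myeloid median was 1.11 and 4.19 with pseudocounts of 5 and 0.1 and 3.96 with a mean of at least 5 FPKM, and the latter left the lower tail with a pseudocount of 5 (-0.16), no filter (-0.43), a mean of at least 5 FPKM (-0.25) and the GC trend removed (-0.53). The B cell list, mostly MHC class II genes and Cd74, went another way, at 0.28 and percentile 67.1 in the CXCR5+ and -4.18 and percentile 0, or -0.86 with no filter, in the CXCR5- library. The counts at least 2-fold higher and lower were 1991 and 2205 for CXCR5+ and 1530 and 1198 for CXCR5- cells. Centred on the median gene, which was at 0.13, the CXCR5- counts were 1257 and 1508, and with equal upper quartiles 1305 and 1497. The side with more rows also turned for CXCR5+ cells, to 2197 and 2055 with equal sums, 1423 and 1404 with a mean of at least 5 FPKM, and 1215 and 1062 with a pseudocount of 5. Both subsets were set against the same naive library.

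The subsets were last compared with Armstrong cells, which sets infection by one strain beside the other; the days after infection and the antigen specificity of the cells are not given in the sources used here. Interferon stimulated genes were higher in both subsets, with 13 of 29 at least 2-fold higher and 0 at least 2-fold lower in each, and medians of 0.88 for CXCR5+ and 0.97 for CXCR5- cells, both at percentile 100. Isg15 was at 44.4 and 25.8 FPKM against 8.16 FPKM, and Ifit3 at 69.2 and 81.6 FPKM against 17.9 FPKM. Early response genes had medians of 0.66 and 0.50, both at percentile 100, with 9 and 5 of 21 genes at least 2-fold higher: Fos was at 25.2 and 68.2 FPKM against 1.56 FPKM, and Jun at 17.5 and 29.8 FPKM against 2.77 FPKM. The shared Armstrong library was itself low against naive for early response genes, at -0.46 and percentile 0.245, and the subsets lay within the random range against naive, at 0.27 and percentile 89.8 and at -0.04 and percentile 40.9. For interferon stimulated genes Armstrong cells were at -0.24 and percentile 0.310 against naive, and the subsets at 0.68 and 0.83, at percentiles 99.96 and 100. Inhibitory and exhaustion associated genes had medians of 0.42 and 0.36, both at percentile 100, with Tox, a transcription factor of exhausted T cells, at 26.4 and 19.9 FPKM against 6.28 FPKM and Pdcd1 at 95.7 and 80.4 FPKM against 36.6 FPKM. Cytotoxic effector genes were at -0.70 and percentile 0.040 in CXCR5+ cells, with 7 of 25 at least 2-fold lower, and at -0.28 and percentile 27.7 in CXCR5- cells, with 1 lower, Gzma. With the GC trend removed both lay in the lower tail, at -0.59 and percentile 0.9 and at -0.46 and percentile 0.1. Mitosis genes were at -0.43 and percentile 7.77, or -0.39 and percentile 2.20 with a pseudocount of 5, in CXCR5+ and -0.55 and percentile 0 in CXCR5- cells. The follicular helper list, which holds Cxcr5 and Pou2af1, was at 0.81 and percentile 100 in CXCR5+ cells and at 0.35 and percentile 99.84 in CXCR5- cells. Of its 14 genes 5 and 3 were at least 2-fold higher and 0 at least 2-fold lower.

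Extl2, Tmem141 and E2f3 were among the 6 named genes lowest in both subsets, which share the Armstrong library, with Klrc3, Insl3 and Klhdc1 in CXCR5+ and Lyz2, Cd74 and H2-Aa in CXCR5- cells; E2f3 was at 3.56 and 1.58 FPKM against 33.4 FPKM. Hspa1b, Aim2, Fosb and Tmsb15l were among the highest in CXCR5- cells, and Mzb1, Chil3, Lcn2, Igj, Hbb-bt and Spi1 the highest in CXCR5+ cells. Plasma cell and myeloid markers had medians of 2.71 and 2.19 in CXCR5+ cells, both at percentile 100, or 1.55 and 1.20 with a pseudocount of 5 and 4.67 and 3.34 with one of 0.1. In CXCR5- cells they were at 0.02 and percentile 74.0 and at -0.57 and percentile 0.385. The B cell list was at 2.29 and percentile 100 in CXCR5+ and at -1.79 and percentile 0 in CXCR5- cells. The counts at least 2-fold higher and lower were 754 and 1020 for CXCR5+ and 535 and 607 for CXCR5- cells. The median gene with a mean of at least 10 FPKM was at -0.29 and -0.19, and centred on it the counts were 1063 and 460 for CXCR5+ and 802 and 397 for CXCR5- cells; with equal upper quartiles they were 935 and 595, and 704 and 418. With each library scaled to the same sum the counts were 950 and 595 for CXCR5+ and 611 and 485 for CXCR5- cells, and with a pseudocount of 5 the CXCR5+ counts were 400 and 379.

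**Figure D3:**
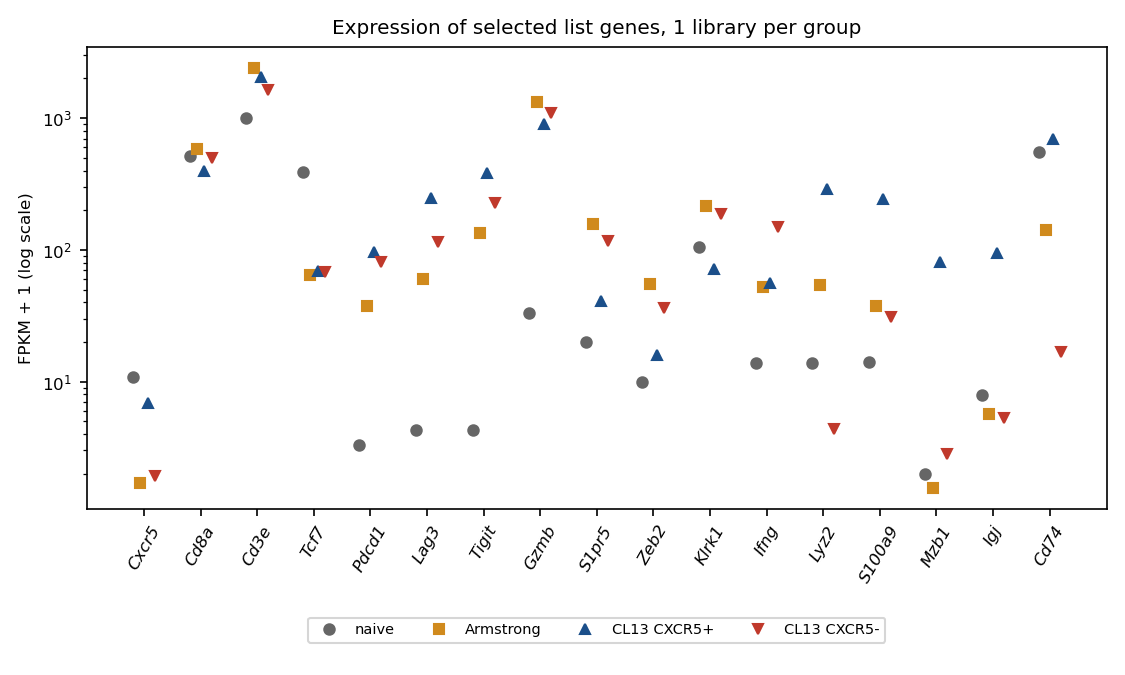
FPKM + 1 on a log axis for genes of the fixed lists in the naive, Armstrong, CXCR5+ and CXCR5- libraries, 1 point per library. Lyz2 is at 289 FPKM in the CXCR5+ and 3.35 FPKM in the CXCR5- library, and Cd8a is between 398 and 584 FPKM in all 4.

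The ratio of CXCR5+ to CXCR5- cells was set against that of naive to Armstrong cells, pairs that share no library. Across 11971 rows Pearson r was -0.18 and Spearman rho -0.27. Of 386 named genes at least 2-fold higher in CXCR5+ than CXCR5- cells, 72 were at least 2-fold higher in naive than Armstrong cells, against 37.7 for independent lists, and 94 at least 2-fold lower, against 68.9. Of 716 named genes lower in CXCR5+ cells, 175 were higher in naive cells, against 69.9, and 55 lower, against 128. The GC trend was left in these counts and acts on both ratios, so a gap from independent lists need not reflect a shared program.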

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

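The tests of other cells, of the GC trend on the plasma cell and myeloid markers, and of fewer T cells were chosen only after the result was seen, and the test of other cells was parted into myeloid and plasma cells after its values were seen; for the GC test on the cytotoxic genes the bounds were set before, and which bound had to be passed by more than the SD across genes was settled after its value was seen.

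Immunoglobulin segments, which entered the counts of rows but no gene list median and no named gene, summed to 40487 FPKM in the CXCR5+ library, against 508 FPKM in the naive, 1172 FPKM in the Armstrong and 1084 FPKM in the CXCR5- library. They made up 6.28% of the CXCR5+ library's FPKM. Igkc was at 15242 FPKM and Ighg2c at 2863 FPKM; segments share sequence, so single values are less certain than the sum.

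Plasma cell and myeloid transcripts were higher in the CXCR5+ library. The GC trend as fitted is small beside these ratios and does not account for them. With it removed the 19 markers had a median log2 ratio of 2.99 (SD 1.54 across genes), against 2.84 before. A removal of that size could not have brought the median under 2-fold, so the outcome was fixed in advance. Myeloid cells, or their free RNA, in the sorted pool may be a source: of 18 myeloid markers outside the lists, taken with no filter, 13 were at least 2-fold higher, with Cst3 at 212 against 69.5 FPKM and Ifitm3 at 158 against 12.4 FPKM, 4 of the 18 were at 10 FPKM or more in the CXCR5- library too, and a sort on CD8 would be meant to remove such cells. For plasma cells, or their free RNA, 2 of 6 such markers were at least 2-fold higher, so plasma cells in the pool and transcripts carried by other cells cannot be told apart with so few markers, 3 of them at 10 FPKM or more in the CXCR5- library. CD8 T cells that carry the transcripts stay open and were not tested.

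Cytotoxic effector genes Klre1, S1pr5, Klrk1, Klrd1 and Zeb2 were at least 2-fold lower in the CXCR5+ library, with a median of -1.38. Fewer T cells in the pool do not account for it, since the 9 identity genes other than Cxcr5 had a median of -0.054 (SD 0.28), where a 2-fold dilution needs -1. With the GC trend removed the median of the 5 was -1.16 (SD 0.38), past the -0.5 set for the trend as the whole cause by more than the SD. No other outcome was possible, since the 5 were picked for being at least 2-fold lower and the removal shifts a gene by a limited amount. Klrd1, for example, went from -1.26 to -0.68. The bound therefore decides nothing, and the values show only that the fitted trend is smaller than these ratios. The trend may account for part, since Klrk1 and Klrd1, at -0.96 and -0.68, then lay within 2-fold. A difference between the subsets themselves stays open as untested.

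For 6 named genes the subsets lay on opposite sides of the naive library by at least 2-fold, a difference that was not tested. The log2 ratios to naive in CXCR5+ and CXCR5- cells were 4.38 and -1.68 for Lyz2, 3.79 and -1.10 for Slpi, 2.99 and -1.95 for Spi1, 1.41 and -1.67 for Hbb-bt, -1.29 and 1.48 for Gadd45a, and -2.16 and 1.60 for Klrc3. Some rest on low values: against naive, Spi1 was at 0.0932 and 3.21 FPKM and Slpi at 0.937 and 3.14 FPKM in CXCR5- cells. Gadd45a was at 0.609 FPKM in CXCR5+ and 2.93 FPKM in naive cells. Such ratios shrink with a larger pseudocount. These ratios to naive are not among the 84 checked under the alternatives.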

How the results depend on the processing

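Counts of rows at least 2-fold apart depended on the pseudocount, on a stricter filter and on which rows were counted. With a pseudocount of 5 the 6 counts were 849 (CXCR5+ against CXCR5-, 1823 in the main analysis), 1856 (Armstrong against naive, 3496), 2277 (CXCR5+ against naive, 4196), 1253 (CXCR5- against naive, 2728), 779 (CXCR5+ against Armstrong, 1774) and 368 (CXCR5- against Armstrong, 1142), since a larger pseudocount shrinks the ratios of low genes. With a pseudocount of 0.1 the CXCR5- against Armstrong count was 1773. With a mean of at least 5 FPKM, which leaves 8852 rows, the counts were 1122, 1729, 1094 and 603 for CXCR5+ against CXCR5-, CXCR5- against naive, CXCR5+ against Armstrong and CXCR5- against Armstrong. With named genes alone, chosen after seeing the data, they were 1102 for CXCR5+ against CXCR5-, 1080 for CXCR5+ against Armstrong and 640 for CXCR5- against Armstrong. For CXCR5+ against CXCR5- in particular, equal sums gave 843 higher and 875 lower, centring on the median gene 800 and 933, and removal of the GC trend, also chosen after seeing the data, 695 and 893. Among list medians of CXCR5+ against CXCR5- cells, the follicular helper median left the upper tail with a pseudocount of 5 (0.16), a mean of at least 5 (0.19), narrowly, with equal sums (0.40), which moved the median gene by 0.12, and without Cxcr5 and Pou2af1 (0.19), and was further in it, at 0.50, with the GC trend removed; the inhibitory list did so with a mean of at least 5 (0.20) and the DNA replication list with a pseudocount of 5 (0.12). Mitosis genes entered it with a pseudocount of 5 (0.13), a mean of at least 5 (0.17) and the GC trend removed (0.19), the chemokine and homing list with the GC trend removed (0.26), and early response genes entered the lower tail (-0.36, percentile 1.94) with it removed. Glycolysis and ribosomal protein medians stayed in their tails under every alternative run. Of the other comparisons, mitosis medians against naive with a pseudocount of 5 were 1.98 in Armstrong and 1.51 in both CXCR5+ and CXCR5- cells, and 3.11 in CXCR5+ cells with one of 0.1. With a mean of at least 5 the inhibitory median of Armstrong against naive was 1.63 and the follicular helper medians against naive were -2.43 in CXCR5+, which entered the lower tail, and -2.28 in CXCR5- cells, whose median left it with no filter (-0.25). Against Armstrong cells, mitosis genes of CXCR5+ cells entered the lower tail with a pseudocount of 5 (-0.39), and cytotoxic genes of CXCR5- cells did so with the GC trend removed (-0.46). Except where stated, the cause was not tested. Pearson r of the disjoint pairs ran from -0.22 to -0.14. None of the 84 ratios of named genes turned sign, and all were at least 2-fold under every alternative that kept the gene, but 75 moved by more than 1.5-fold with a pseudocount of 5, 40 with one of 0.1 and 2 with the length trend removed. The 84 were picked as the ratios furthest apart, so their staying at least 2-fold was largely fixed by that choice. Of 35 genes of the program lists at least 2-fold apart between the subsets, 16 were under 2-fold with a pseudocount of 5, 15 with the GC trend removed, 5 with equal sums, 3 with centred ratios, 2 with the length trend removed and 1 with equal upper quartiles. Read depth is unknown, so what it limits could not be given.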

Other observations

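The removal of the GC trend was chosen only after the result without it was seen; the bound on its outcome was set before that outcome was seen.

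Mitochondrial rows made up 11.4% of FPKM in the naive, 5.43% in the Armstrong, 3.64% in the CXCR5+ and 8.33% in the CXCR5- library. Of 35 nuclear respiratory chain genes, 4 were at least 2-fold lower in CXCR5+ than CXCR5- cells and 0 at least 2-fold higher: Uqcrb was at 38.8 against 163 FPKM, Ndufa4 at 226 against 651 FPKM, Cox7b at 33.9 against 95.6 FPKM and Atp5j at 86.5 against 195 FPKM, although the list's median was 0.09. Across 11971 rows the libraries were nearest for Armstrong and CXCR5- cells, with Pearson r 0.94 on the log2 scale. They were furthest for naive and CXCR5+ cells, with 0.75. CXCR5+ and CXCR5- cells had 0.86, and naive and CXCR5- cells 0.87. Immunoglobulin and myeloid transcripts and the GC trend were left in, so the values compare libraries and not T cells alone.

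A hypothesis was that CXCR5+ cells differ from CXCR5- cells in the direction in which naive cells differ from effector cells, and that the GC trend hides it, since GC content acts on these ratios in opposite directions. With the trend removed from both, Pearson r across genes was -0.14, against -0.18 before, so no positive relation appeared. For these libraries the value argues against a positive relation across genes that the trend as fitted hides. For the T cells themselves it cannot decide the hypothesis. Immunoglobulin and myeloid transcripts were left in, and no group had a replicate library. Among named genes at least 2-fold higher in CXCR5+ cells, without the removal, there was an excess of genes higher in naive cells, 72 against 37.7 for independent lists, and also of genes higher in Armstrong cells, 94 against 68.9. Among those lower in CXCR5+ cells, also without the removal, 175 were higher in naive cells against 69.9 and 55 higher in Armstrong cells against 128. The trend left in these counts itself makes genes with little GC lower in CXCR5+ cells and higher in naive than Armstrong cells. The counts therefore cannot speak for or against the hypothesis.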
